A study of Mus musculus with 9 samples.

How the data were processed

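Strand-specific total RNA libraries, depleted of ribosomal RNA, were prepared from mouse pancreatic stellate cell lines with a TruSeq kit after RNA extraction with a PureLink kit, per the labels' protocols. Cells of C57BL/6J origin were cultured for 4 days in control medium of DMEM with 5% FBS (MG-CM), in tumour organoid conditioned medium (CM), or in CM with 500 nM AZD1480 (CM-JAKi), with 3 replicates each. Replicate 1 used PSC4 and replicates 2 and 3 used PSC5-I and PSC5-II, together called PSC5 where a term or difference of line was tested, and an independent source of conditioned medium served each replicate number. The replicates are therefore separate cultures and medium sources, and line and source change together. The FBS content of CM was not stated apart from that of the control.

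The submitters' processing notes name STAR 2.5.1b, RSEM 1.2.29 and DESeq2 and the mouse builds NCBIM37 and mm9, without their roles. The deposited values were read as gene counts of the kind "expected counts" made by the authors, estimates rounded to whole numbers and not scaled between libraries, from the values themselves and from RSEM being named. The table held 17156 gene symbols for 9 libraries. Every gene had counts in at least 2 libraries and a total of at least 2, so a filter before deposition cannot be ruled out. Totals were 25625806 to 32466018 counts per library, and 15678 to 15944 genes had a count in each. Mitochondrial transcripts held 1.53% to 1.90% of counts, the 10 highest genes 4.28% to 6.95%, and Lars2 alone 0.646% to 2.06%. Genes are given by symbol without coordinates, since the reference at hand was of another build. Estimated counts divide reads between near-identical genes, so single values of Apol9a, Apol9b, Oas1a and Tgtp2 are uncertain. Counting intervals are exact 95% intervals and cover counting error only.

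Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes were filtered with filterByExpr on the group (minimum count 10, minimum total 15), which kept 13613. Libraries were scaled by TMM. All 9 libraries entered a quasi-likelihood fit with a term per group and robust estimation, because 3 libraries per group leave few degrees of freedom. The comparisons were CM against MG-CM, CM-JAKi against CM and CM-JAKi against MG-CM, each by a quasi-likelihood F-test with Benjamini-Hochberg adjustment over the genes kept, and genes were called at an adjusted p under 0.05. Levels are given as CPM, counts divided by the TMM-scaled library total in the usual units. The log scale used a prior count of 2. With library size alone the median log2 change of all genes was -0.0666, 0.101 and 0.0283 in the 3 comparisons, against 0.00505, 0.00580 and 0.00528 with TMM.

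The labels number the replicates but state no paired model, so the replicate number was not in the fit. Libraries of the same number share a stellate line, and CM and CM-JAKi of that number also a medium source. Differences of line and source therefore count as error in the fit. After group means were removed, libraries of the same number correlated across genes at 0.291 to 0.680 over 9 same-number pairs, each higher than with any other number. A fit with the number as a block was the alternative, and its values are given for the counts of each comparison, for described genes and lists whose call it changed, and for some of the list counts. Chi-square values per degree of freedom between replicates of a group were 15.3 to 109.

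Choices of tests, gene lists, named genes and alternatives were made before the data were examined, except for those said to be added. A set of 27 gene lists was written from general knowledge, covering signalling, inflammation, contraction, matrix, metabolism, stress, cell identity, other cell types and RNA quality. Lists with at least 5 genes kept were tested with camera of limma on log2 CPM, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the 26 lists tested. The acinar and endocrine list kept 2 of 20 genes and was not tested. Camera was repeated with a correlation estimated per list, and fry of limma gave directional p values. Under the estimated correlation 0 lists were called in any comparison. At an unadjusted p under 0.05 it gave 0, 3 and 3 lists, and fry called 9, 11 and 3.

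Genes were named by a fixed rule. In each comparison it took the 10 highest and 10 lowest fold changes among called genes with a mean log2 CPM of at least 2 and the same direction in 3 pairs, without predicted or unnamed genes. It added up to 4 members of each list with the smallest p, the 10 largest products of opposite changes, and 15 cytokine, JAK-STAT, contractile and TGF-beta genes whatever their result. Of these 15 Il1a was not kept by the filter and has no value. Single values of 2 genes are not reported here. The genes of the retinoid and fatty acid lists in the closing section were named after the values of other genes were seen. Where a gene had few counts in a group, its ratio is given with a counting interval.

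The overlap of opposite changes was compared with that of independent lists, and their correlation and covariance with 20 simulations of counts with no effect. Median changes with the inhibitor were computed over genes changed at least 2-fold in CM, and again for genes picked in 2 replicates and measured in the third. Differences between PSC4 and PSC5 were tested as an interaction in the block fit with 2 residual degrees of freedom, and rest on a single PSC4 library per group. Alternatives were the block, a cell line term, DESeq2 size factors, the DESeq2 test, limma-voom, no filter, a stricter filter of 1 CPM in 3 libraries, fits of only the groups compared, and the omission of each library and each replicate number. Single libraries were left out only in the fit without the block. Such a fit has a smaller group and counts differences of line as error. A lost call need not mean that the change rests on the library left out. The group labels were also split in all 10 ways.

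The procedure was tested on simulated data with the dispersions of the table. Of 100 genes changed 2-fold, 64%, 73% and 64% were recovered in the 3 comparisons, and of 100 changed 4-fold, 85%, 90% and 94%, with 10, 8 and 8 false calls among the unchanged genes. With the block there were 14, 10 and 14 false calls. No replicate effect was simulated, so these counts cannot decide between the fits with and without the block. The interaction test recovered 72 of 100 genes with a log2 difference of 2 and 85 of 100 with a difference of 3, with 14 false calls. A cell cycle list raised 2-fold was called and 0 of 24 other lists tested with it were. No control medium with inhibitor was among the libraries, and reads were not analysed here.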

Results

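Total RNA was sequenced from mouse pancreatic stellate cells, fibroblast-like cells of the pancreas that become matrix-producing cells in injury and cancer. Cells of C57BL/6J origin were cultured for 4 days in 1 of 3 conditions, with 3 libraries each. The control was a medium of DMEM with FBS, labelled MG-CM. The other conditions were medium conditioned by pancreatic tumour organoids (CM) and such medium with 500 nM AZD1480, a JAK kinase inhibitor (CM-JAKi). Replicate 1 came from the stellate line PSC4 and replicates 2 and 3 from PSC5-I and PSC5-II, each replicate with its own source of conditioned medium. The libraries held 28327256, 29121630 and 26672965 counts in MG-CM replicates 1, 2 and 3, 30591103, 32466018 and 32031176 in CM, and 31451138, 32089373 and 25625806 in CM-JAKi. On the first principal component, which held 48.8% of the variance of log2 CPM (counts scaled to library size), the CM libraries lay at -79.5, -37.6 and -35.8 and the remaining libraries between -0.722 and 47.4. Fold changes are given on the log2 scale with their standard errors and CPM values as mean ± SD (n = 3). Every single gene described as risen or fallen had an adjusted p under 0.05 and moved in that direction in 3 of 3 same-numbered pairs. Counts of genes that rose or fell under another fit or adjustment are given with its name.

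The comparison of CM with MG-CM asks what medium conditioned by tumour organoids changes in stellate cells. Stellate cells in CM expressed more of most interferon-stimulated and cholesterol synthesis genes, and of some chemokines and genes of glycolysis and amino acid supply. They expressed less of some contractile, pericyte and smooth muscle genes. Collagen and matrix genes moved both ways. With a correlation estimated per list none of the list calls held, while fry called 9 lists. Of 13613 genes tested, 660 were higher and 734 lower in CM (edgeR quasi-likelihood F-test, Benjamini-Hochberg adjusted p under 0.05), and 298 and 331 of them differed at least 2-fold. DESeq2 called 1207 higher and 1309 lower, and edgeR with the replicate number as a block called 1573 and 1747. Of the 1394 called genes, 1393 moved in the same direction in all 3 same-numbered pairs. Without MG-CM replicate 2 the counts were 45 higher and 86 lower. They were 396 and 377 without MG-CM replicate 1, 283 and 405 without MG-CM replicate 3, and 309 and 384 without CM replicate 1. Of the 98 named genes called here, 23 were called without each library in turn, and leaving out MG-CM replicate 2 ended 75 of the calls. Single libraries were left out without the block, here and below. Leaving out all of replicate 2 gave 6 higher and 2 lower genes without the block. With the block, in a fit added after the data were seen, it gave 243 and 237.

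**Figure D1:**
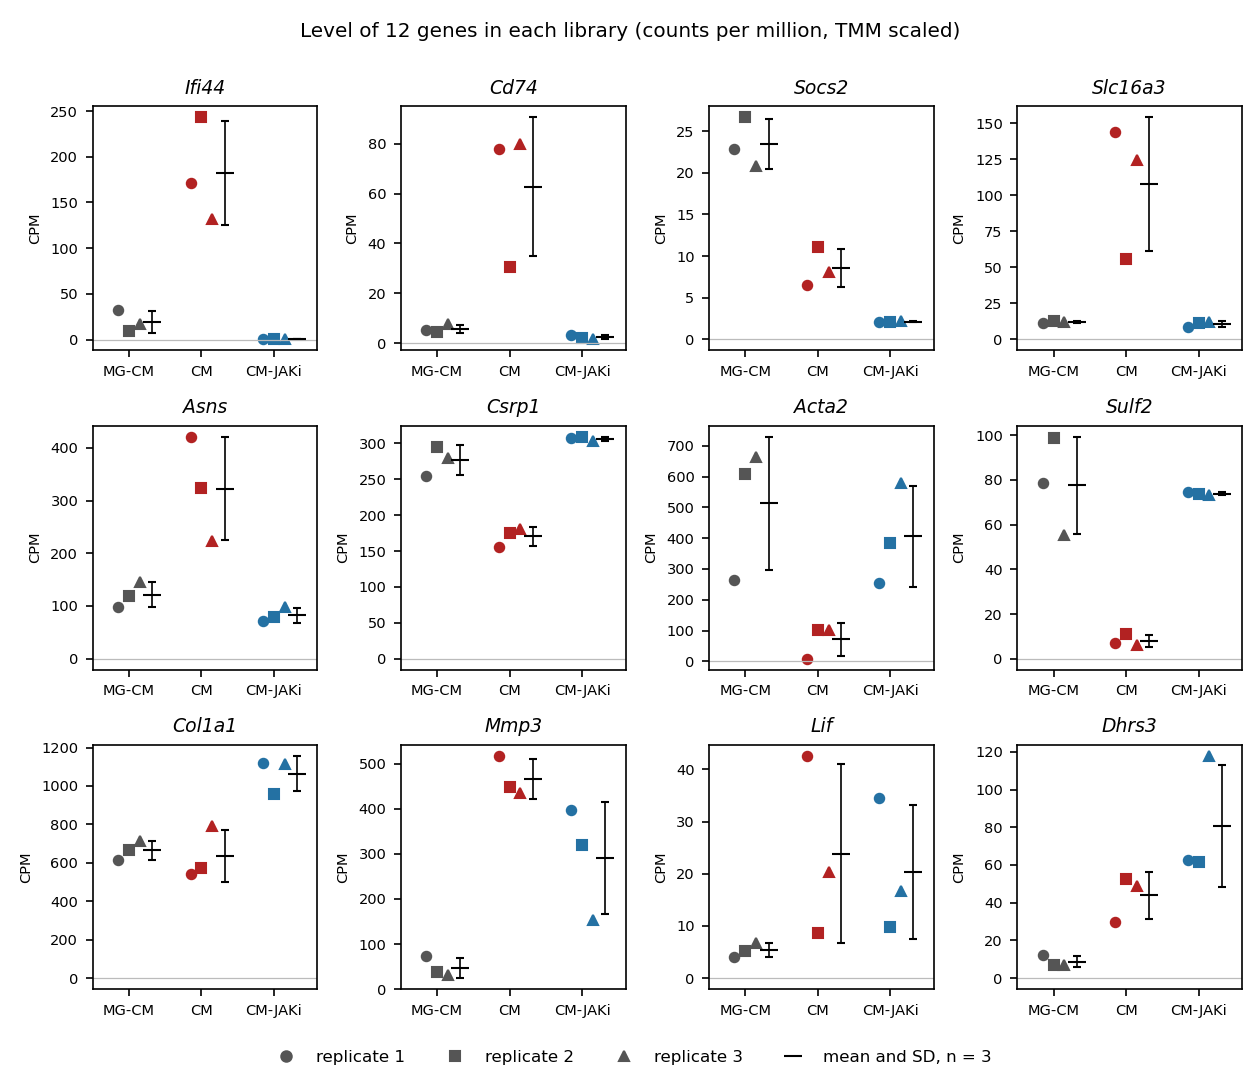
Levels in CPM (linear axis) of 12 genes in each library of MG-CM, CM and CM-JAKi, with points for libraries and bars for the mean and SD of 3 libraries. Slc16a3 averaged 12 CPM in MG-CM, 108 in CM and 10.7 in CM-JAKi, while Dhrs3 averaged 8.77, 43.8 and 80.7.

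The interferon response had the largest share of raised members among the tested lists. Of its 36 tested members 30 rose, or 34 adjusted over the list alone (median log2 fold change 1.65, camera adjusted p = 1.6e-22, adjusted p = 0.332 with an estimated correlation). Ifi44 rose from 19.4 ± 11.9 to 182 ± 56.5 CPM, a change of 3.23 ± 0.43 (adjusted p = 0.00841). The antiviral genes Rsad2 and Oas1a rose by 2.86 ± 0.37 and 2.47 ± 0.31. Of 17 antigen presentation genes 5 rose, 6 adjusted over the list alone and 9 with the replicate block (median log2 fold change 0.46, camera adjusted p = 3.82e-05, adjusted p = 0.332 with an estimated correlation). Cd74, the invariant chain of MHC class II, rose from 5.8 ± 1.67 to 62.8 ± 27.8 CPM (adjusted p = 0.00652). The class I gene H2-T23 rose by 1.86 ± 0.17. Each of the 5 genes named in this paragraph was called without each library in turn.

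Of 27 inflammatory fibroblast cytokines and chemokines, 9 rose, or 20 with the replicate block. Adjusted over the list alone, 21 were higher and 2 lower (median log2 fold change 1.75, camera adjusted p = 1.46e-07, adjusted p = 0.332 with an estimated correlation). The T cell chemoattractant Ccl5 rose from 17.4 ± 4.64 to 56.7 ± 10.1 CPM (adjusted p = 0.00734) and kept its call without each library. Cxcl10 rose from 39.2 ± 13.5 to 192 ± 79.6 CPM, but not without MG-CM replicate 2 (adjusted p = 0.052). Cxcl1 was called higher too, but leaving out any single library except CM replicate 2 ended its call. Il6 averaged 2.29 CPM in MG-CM and 16.5 in CM, higher in 3 of 3 pairs, and was not called (adjusted p = 0.0889, 0.0224 with the block). Lif was higher in 3 of 3 pairs and was not called either (log2 change 2.15 ± 0.61, adjusted p = 0.0592, 0.0301 with the block, 0.0329 without CM replicate 2). Il1r1, the receptor of interleukin 1, changed by 0.45 ± 0.37 without a call (adjusted p = 0.477).

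Of 21 JAK-STAT targets and receptors, 7 rose and 1 fell, with 11 and 2 adjusted over the list alone (median log2 fold change 0.50, camera adjusted p = 0.00956, adjusted p = 0.511 with an estimated correlation). The member that fell was Socs2, an inhibitor of cytokine signalling, from 23.4 ± 2.97 to 8.57 ± 2.27 CPM (adjusted p = 0.00791). Socs3 rose by 0.84 ± 0.17, but lost its call without MG-CM replicate 2 (adjusted p = 0.0988), MG-CM replicate 3 (0.0596) or CM replicate 1 (0.061). Neither Stat3 nor Jak1 was called, with log2 changes of 0.24 ± 0.11 and -0.07 ± 0.09 (adjusted p = 0.184 and 0.645). Jak2 was called with the block or the cell line term but not otherwise (log2 change 0.61 ± 0.27, adjusted p = 0.187, 0.00744 with the block). Of 24 NF-kB targets 3 rose, 3 adjusted over the list alone and 9 with the block (median log2 fold change 0.30, camera adjusted p = 0.00861, adjusted p = 0.511 with an estimated correlation). These were Relb, Nfkbiz and Sod2, and without MG-CM replicate 2 none of the 3 was called (adjusted p = 0.0962, 0.0868 and 0.117). Without MG-CM replicate 3 they lost their calls as well (0.0569, 0.0608 and 0.0583), as did Relb and Sod2 without MG-CM replicate 1 (0.0538 and 0.0679), Nfkbiz and Sod2 without CM replicate 1 (0.0683 and 0.0745) and Sod2 without CM replicate 3 (0.0575). Of 18 acute phase and complement genes 2 rose, Lrg1 and Cp, with 7 adjusted over the list alone and 8 with the block, where 1 gene fell (median log2 fold change 0.79, camera adjusted p = 0.0124, adjusted p = 0.537 with an estimated correlation). Leaving out MG-CM replicate 2 ended the call of Lrg1 (adjusted p = 0.0701). Cp lost its call without each of the 6 libraries in turn (adjusted p = 0.0975, 0.13, 0.0702, 0.0503, 0.075 and 0.0872 without MG-CM replicates 1, 2 and 3 and CM replicates 1, 2 and 3). Without replicate 3 the JAK-STAT list (adjusted p = 0.0612) and the acute phase list (0.0680) lost their calls.

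Of 28 cholesterol and fatty acid synthesis genes 21 rose, or 25 adjusted over the list alone (median log2 fold change 0.77, camera adjusted p = 3.17e-15, adjusted p = 0.332 with an estimated correlation). Of 30 amino acid and ER stress response genes 13 rose, or 23 adjusted over the list alone (median log2 fold change 0.70, camera adjusted p = 5.96e-11, adjusted p = 0.332 with an estimated correlation). Asns, which makes asparagine, rose from 122 ± 23.6 to 323 ± 98.5 CPM. Of 32 hypoxia and glycolysis genes 14 rose, with 24 higher and 1 lower adjusted over the list alone (median log2 fold change 0.76, camera adjusted p = 8.02e-09, adjusted p = 0.332 with an estimated correlation). The lactate exporter Slc16a3 rose from 12 ± 0.822 to 108 ± 46.3 CPM (log2 change 3.17 ± 0.33, adjusted p = 0.00545) and kept its call without each library. Vegfa and Pfkl rose by 1.23 ± 0.23 and 1.21 ± 0.21. Without MG-CM replicate 2 the adjusted p was 0.0666 for Asns, 0.0829 for Vegfa and 0.071 for Pfkl.

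Of 22 contractile myofibroblast genes 5 fell, 13 adjusted over the list alone and 18 with the block (median log2 fold change -0.73, camera adjusted p = 3.12e-07, adjusted p = 0.351 with an estimated correlation). Csrp1, a LIM protein of smooth muscle, fell from 277 ± 20.4 to 170 ± 13.3 CPM (adjusted p = 0.00791) and kept its call without each library. Acta2, which encodes smooth muscle actin, averaged 513 ± 217 CPM in MG-CM and 71.7 ± 54.5 in CM. It was lower in 3 of 3 pairs and missed the threshold (adjusted p = 0.0556), but was called with the block (0.00965), by DESeq2 (0.0081) and without CM replicate 1 (0.0349). Of 11 pericyte and smooth muscle markers 3 fell, with 1 higher and 7 lower adjusted over the list alone and 1 higher and 5 lower with the block (median log2 fold change -1.07, camera adjusted p = 0.0035, adjusted p = 0.332 with an estimated correlation). The markers that fell were Lmod1, which is also on the contractile list, Synpo2 and Smtn. Lmod1 lost its call without MG-CM replicate 2 (adjusted p = 0.0771). Smtn lost its call without each of the 6 libraries in turn (adjusted p = 0.0579, 0.169, 0.101, 0.0669, 0.109 and 0.105 without MG-CM replicates 1, 2 and 3 and CM replicates 1, 2 and 3), and Synpo2 without each except MG-CM replicate 1 (0.153, 0.103, 0.0857, 0.0666 and 0.0632, in the same order).

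The matrix and TGF-beta lists were not called and had members on both sides. Of 36 collagen and matrix genes 5 rose and 3 fell, 8 and 9 adjusted over the list alone (median log2 fold change -0.11, camera adjusted p = 0.422). Col6a1 fell from 826 ± 123 to 330 ± 82 CPM (adjusted p = 0.00987), while Col1a1 changed by -0.06 ± 0.16 (adjusted p = 0.829). Eln, which encodes elastin, fell from 4.11 ± 0.821 to 0.905 ± 0.428 CPM, but not without MG-CM replicate 2 (adjusted p = 0.0728). Of 25 matrix proteases and inhibitors 5 rose and 6 fell, 10 and 13 adjusted over the list alone (median log2 fold change -0.50, camera adjusted p = 0.825). The mean of this list was 0.30, opposite in sign to its median and to the camera direction. Mmp3, a stromelysin, rose from 47 ± 22.7 to 467 ± 44.2 CPM (adjusted p = 0.00749). Of 25 TGF-beta targets 4 rose and 4 fell, 9 and 7 adjusted over the list alone (median log2 fold change 0.06, camera adjusted p = 0.98). Tgfb3 fell by 1.56 ± 0.20 and kept its call without each library. Ctgf fell from 39.1 ± 11.3 to 12.9 ± 5.07 CPM, but not without MG-CM replicate 2 (adjusted p = 0.0873) or MG-CM replicate 1 (0.0556). Tgfb1 and Tgfbr2 were not called (log2 changes 0.78 ± 0.25 and -0.32 ± 0.18, adjusted p = 0.0796 and 0.283), and with the block the adjusted p was 0.00432 for Tgfb1 and 0.266 for Tgfbr2.

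Of 20 p53 and senescence genes 4 fell, 7 adjusted over the list alone, and with the block 1 rose and 10 fell (median log2 fold change -0.33, camera adjusted p = 0.00773, adjusted p = 0.513 with an estimated correlation). Sesn1, a p53 target, fell by 0.95 ± 0.14 (adjusted p = 0.00984). Among 13 quiescent stellate and adipogenic genes, 1 rose and 2 fell, 2 and 5 adjusted over the list alone. The block gave 1 and 6 and called the list (median log2 fold change -0.99, camera adjusted p = 0.0966, adjusted p = 0.0410 with the block, or 0.381 with an estimated correlation as well), and so did the omission of replicate 2 (adjusted p = 0.0284). The adipocyte gene Fabp4 rose by 3.32 ± 0.51 while Cygb and Plin4 fell, and leaving out MG-CM replicate 2 ended these calls (adjusted p = 0.0503, 0.112 and 0.151). Cygb and Plin4 also lost their calls without MG-CM replicate 1 (0.0793 and 0.102), CM replicate 1 (0.0931 and 0.129) or CM replicate 3 (0.0813 and 0.11), and Plin4 without MG-CM replicate 3 (0.0606). Among 19 fibroblast identity genes 2 rose and 5 fell, and the same numbers held adjusted over the list alone (median log2 fold change 0.01, camera adjusted p = 0.607). The mean of that list was -0.11 and the camera direction lower, opposite in sign to its median. Dcn rose from 375 ± 127 to 2718 ± 1737 CPM, but not without MG-CM replicate 2 (adjusted p = 0.0825) or MG-CM replicate 3 (0.055).

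For 40 cell cycle genes edgeR called 0 in either direction, while 4 were higher and 1 lower at an unadjusted p under 0.05 and DESeq2 called 1 higher and 1 lower (median log2 fold change 0.05, camera adjusted p = 0.422). With the block 4 rose and 2 fell, and without replicate 2 the list was called higher (adjusted p = 0.0305). Of 32 ribosomal protein genes edgeR called 0, 1 was higher at an unadjusted p under 0.05 and DESeq2 called 0 (median log2 fold change 0.13, camera adjusted p = 0.0966). This list was called higher without replicate 2 (adjusted p = 0.00517) and without replicate 3 (0.00771). Of 14 genes of the list named for RNA quality 0 were called by edgeR, by DESeq2 or at an unadjusted p under 0.05 (median log2 fold change 0.03, camera adjusted p = 0.806). This list does not measure RNA integrity. Among markers of other cell types, edgeR called 0 of 8 ductal, 0 of 5 leukocyte and 0 of 8 mesothelial genes. At an unadjusted p under 0.05, 2 ductal, 1 leukocyte and 1 mesothelial genes were higher, DESeq2 called 1, 1 and 0 of them, and the camera adjusted p was 0.532, 0.806 and 0.669. The summed level of the leukocyte list, most of it from Cd14, was 39.6, 25.4 and 35.0 CPM in MG-CM replicates 1, 2 and 3, 112, 36.1 and 52.6 in CM and 37.3, 20.3 and 22.4 in CM-JAKi, here scaled to library size alone. Cd14 averaged 26.8 ± 6.47 CPM in MG-CM and 64.6 ± 44 in CM and was not called (adjusted p = 0.132), except with the block (0.0163), the cell line term (0.0281) and DESeq2 (0.0361). Of 12 endothelial markers 2 fell, 4 adjusted over the list alone, and the list was called lower without replicate 2 alone (median -0.16, camera adjusted p = 0.116, 0.0104 without replicate 2). Of 7 Schwann and neural markers edgeR called 0, with 2 lower at an unadjusted p under 0.05, by DESeq2 and with the block, yet the list was called lower (median log2 fold change -0.43, camera adjusted p = 0.0461, adjusted p = 0.332 with an estimated correlation). It lost that call without replicate 3 (adjusted p = 0.0680) and with no low-count filter (0.0677).

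The largest changes included secreted proteins of both directions. Spp1, which encodes osteopontin, rose from 1298 ± 579 to 13220 ± 8695 CPM, and the collagenase Mmp13 from 1.6 ± 1.49 to 77.6 ± 77.7. Leaving out CM replicate 1 ended the calls of Spp1 (adjusted p = 0.0511) and Mmp13 (0.074). The same held for MG-CM replicate 2 (0.0922 and 0.12) and MG-CM replicate 3 (0.0644 and 0.0906), and for Mmp13 also for MG-CM replicate 1 (0.0534). The heparan sulphatase Sulf2 fell from 77.5 ± 21.8 to 7.96 ± 2.69 CPM (log2 change -3.28 ± 0.27, adjusted p = 0.00236). Nov fell by 3.76 ± 0.54 and Igfbp2 fell by 3.61 ± 0.46, and all 3 kept their calls without each library. Ptn, a heparin-binding growth factor, fell from 262 ± 111 to 17.6 ± 11.3 CPM, but not without MG-CM replicate 2 (adjusted p = 0.0538).

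**Figure D2:**
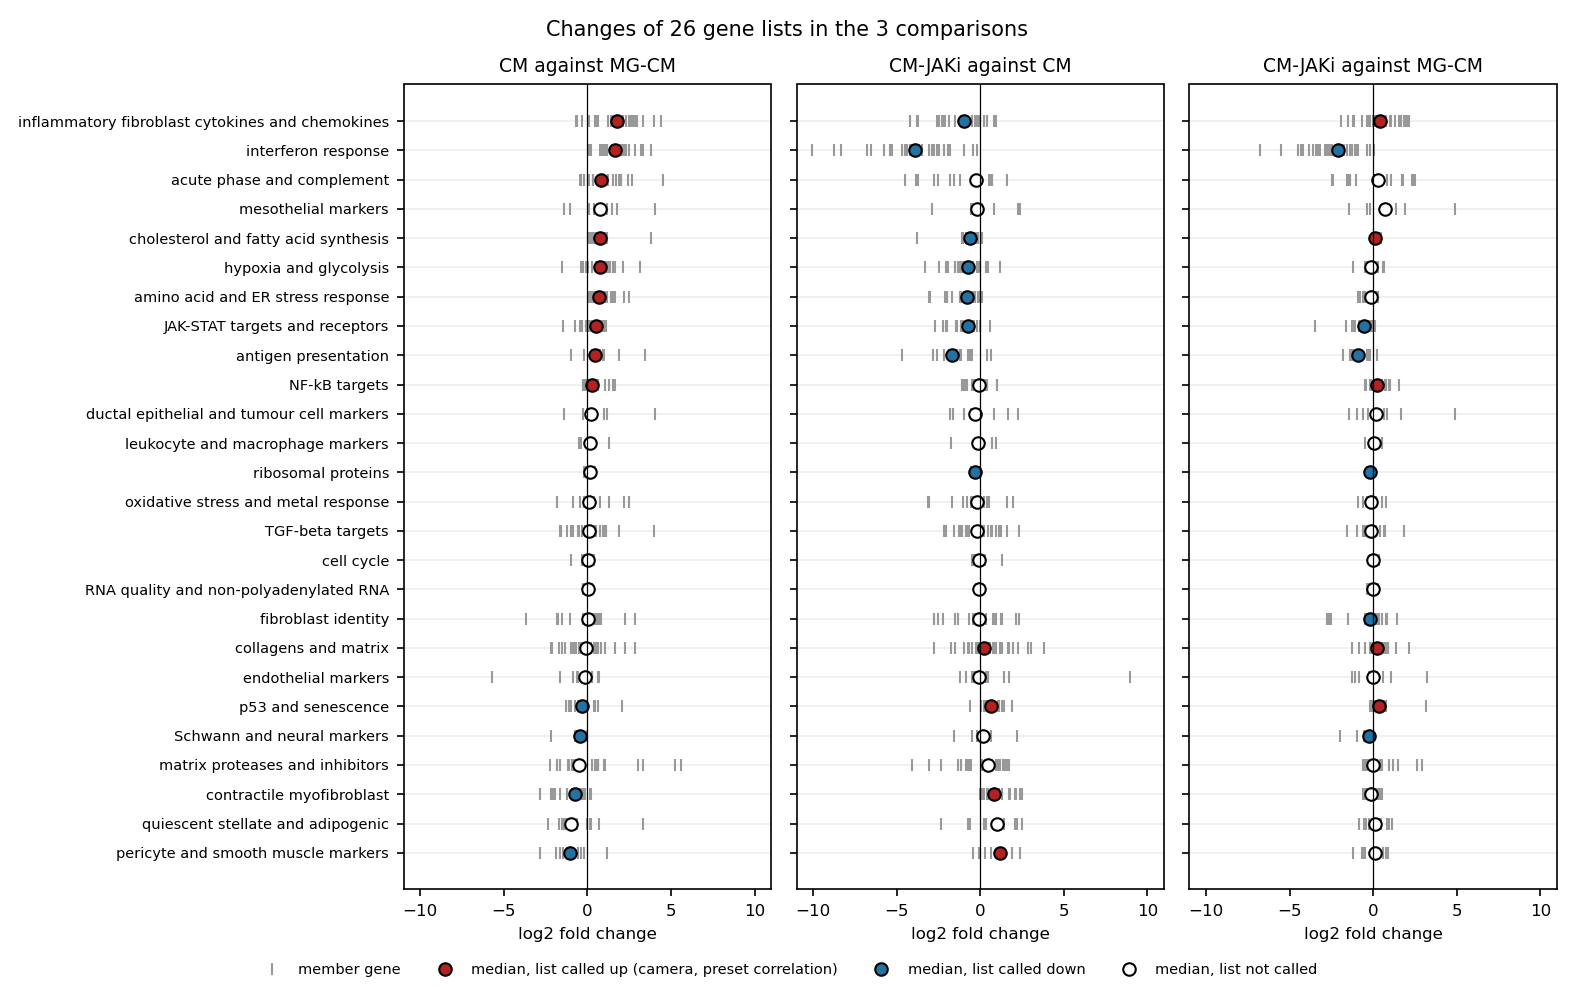
Log2 fold changes of the tested members of 26 gene lists (ticks) and their medians (dots) in the 3 comparisons, with red dots for lists called higher, blue for lists called lower and white for lists not called by camera with the preset correlation. The interferon response median was 1.65 in CM against MG-CM, -3.91 in CM-JAKi against CM and -2.08 in CM-JAKi against MG-CM.

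The comparison of CM-JAKi with CM asks which genes depended on JAK activity in conditioned medium. With the inhibitor, most interferon-stimulated, antigen presentation and JAK-STAT genes of the lists fell in stellate cells. Most of the listed glycolytic, cholesterol and amino acid genes fell as well. Some contractile, pericyte, p53 and collagen genes rose. Here too none of the list calls held with an estimated correlation, while fry called 11 lists. The inhibitor changed more genes than the medium had: 1369 rose and 1216 fell, 522 and 496 of them at least 2-fold. DESeq2 called 1816 and 1727, and the block gave 2529 and 2126. Of the 2585 called genes, 2584 moved in the same direction in all 3 pairs. Without CM-JAKi replicate 2 the counts were 512 higher and 479 lower, without CM replicate 1 773 and 739, and without CM-JAKi replicate 3 818 and 703. Of the 122 named genes called here, 87 were called without each library in turn, and leaving out CM-JAKi replicate 2 ended 30 calls.

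Of the 36 interferon response genes 34 fell, or 35 adjusted over the list alone (median log2 fold change -3.91, camera adjusted p = 1.72e-36, adjusted p = 0.219 with an estimated correlation). Ifi44 fell from 182 ± 56.5 to 0.42 ± 0.0821 CPM (adjusted p = 0.00015) and Ifi27l2a fell by 5.48 ± 0.25. Oas2 had 5832 counts summed over the CM libraries and 5 over the CM-JAKi libraries, a depth-scaled ratio of 9.14e-04 with a counting interval of 2.97e-04 to 0.00213. Of 17 antigen presentation genes 14 fell, and 14 adjusted over the list alone (median log2 fold change -1.68, camera adjusted p = 1.61e-10, adjusted p = 0.219 with an estimated correlation). Cd74 fell to 2.4 ± 0.817 CPM and the immunoproteasome gene Psmb8 fell by 2.80 ± 0.22. Of 21 JAK-STAT targets and receptors 17 fell, and adjusted over the list alone 18 fell and 1 rose (median log2 fold change -0.72, camera adjusted p = 1.61e-10, adjusted p = 0.219 with an estimated correlation). Socs3 fell from 136 ± 35 to 32.6 ± 2.27 CPM (adjusted p = 0.000349) and Socs2 to 2.13 ± 0.0639. Jak2 fell by 1.45 ± 0.28, and Il4ra, a subunit of the interleukin 4 receptor, fell by 2.21 ± 0.24. Stat3 fell by 0.51 ± 0.11, but not without CM-JAKi replicate 2 (adjusted p = 0.0674). Jak1 was called lower too, but leaving out any single library except CM-JAKi replicate 1 ended its call. All other genes named in this paragraph kept their calls without each library.

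Cytokines split. Of 27 inflammatory fibroblast genes 7 fell and 2 rose, 10 and 2 adjusted over the list alone and 13 and 2 with the block (median log2 fold change -0.96, camera adjusted p = 0.00179, adjusted p = 0.541 with an estimated correlation). Cxcl10 fell to 34.6 ± 3.03 CPM and Ccl5 to 25 ± 3.01, and Il33, an alarmin, fell from 190 ± 67.3 to 14.6 ± 9.86. Has2, which makes hyaluronan, fell by 2.57 ± 0.32, and these 4 genes kept their calls without each library. Il6 was lower in 3 of 3 pairs and was not called, except with the block or the cell line term (log2 change -2.09 ± 0.90, adjusted p = 0.137, 0.0202 with the block) and without CM-JAKi replicate 1 (0.0175). Lif averaged 20.4 ± 12.8 CPM with the inhibitor and Cxcl1 67.7 ± 25.5, and neither was called (log2 changes -0.23 ± 0.58 and 0.25 ± 0.44, adjusted p = 0.814 and 0.724). Of 18 acute phase and complement genes 5 fell and 2 rose, 7 and 3 adjusted over the list alone, and the list was called with the block (adjusted p = 0.0235, or 0.691 with an estimated correlation as well), with no low-count filter (0.0452) and without replicate 1 (0.0175), but not otherwise (median log2 fold change -0.24, camera adjusted p = 0.076). Of 24 NF-kB targets 1 fell and 2 rose, 1 and 1 adjusted over the list alone and 5 and 2 with the block (median log2 fold change -0.10, camera adjusted p = 0.712).

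Of 28 cholesterol and fatty acid synthesis genes 18 fell, 23 adjusted over the list alone (median log2 fold change -0.61, camera adjusted p = 1.84e-09, adjusted p = 0.385 with an estimated correlation). Of 30 amino acid and ER stress response genes 18 fell, 21 adjusted over the list alone (median log2 fold change -0.83, camera adjusted p = 1.84e-09, adjusted p = 0.385 with an estimated correlation). Asns fell to 82.5 ± 14.2 CPM, Trib3 fell by 3.02 ± 0.41 and the stress factor Atf3 fell by 1.99 ± 0.24. Of 32 hypoxia and glycolysis genes 19 fell, 23 adjusted over the list alone (median log2 fold change -0.75, camera adjusted p = 2.44e-09, adjusted p = 0.385 with an estimated correlation). Slc16a3 fell to 10.7 ± 1.91 CPM (adjusted p = 0.000647), Ero1l fell by 1.53 ± 0.24 and Ndrg1 fell by 0.97 ± 0.15. All 6 genes kept their calls without each library. Of 32 ribosomal protein genes edgeR called 0, while 9 were lower at an unadjusted p under 0.05, 5 by DESeq2 and 3 with the block, and the list was called lower (median log2 fold change -0.33, camera adjusted p = 2.55e-05, adjusted p = 0.712 with an estimated correlation).

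Of 22 contractile genes 6 rose, 12 adjusted over the list alone and 17 with the block (median log2 fold change 0.80, camera adjusted p = 1.42e-05, adjusted p = 0.498 with an estimated correlation). Csrp1 rose from 170 ± 13.3 to 306 ± 3.18 CPM (adjusted p = 0.000918). Acta2 averaged 405 ± 164 CPM with the inhibitor, higher in 3 of 3 pairs, and missed the threshold (adjusted p = 0.0559), but was called with the block (0.0086), by DESeq2 (0.0172) and without CM replicate 1 (0.0336). Of 11 pericyte and smooth muscle markers 3 rose, 6 adjusted over the list alone and 7 with the block (median log2 fold change 1.18, camera adjusted p = 0.01, adjusted p = 0.385 with an estimated correlation). Of 20 p53 and senescence genes 8 rose, 10 adjusted over the list alone and 13 with the block (median log2 fold change 0.62, camera adjusted p = 1.42e-05, adjusted p = 0.385 with an estimated correlation). Phlda3, Sesn1 and the death receptor Fas rose by 1.43 ± 0.26, 1.28 ± 0.14 and 1.12 ± 0.20. Of 36 collagen and matrix genes 12 rose and 4 fell, 13 and 6 adjusted over the list alone (median log2 fold change 0.25, camera adjusted p = 0.0378, adjusted p = 0.541 with an estimated correlation). The list lost its call with the block (adjusted p = 0.0581), without replicate 1 (0.216) and without replicate 2 (0.109). Col1a1 rose from 636 ± 137 to 1064 ± 92.1 CPM (adjusted p = 0.0147), Col6a1 by 1.63 ± 0.19 and Col15a1 by 3.80 ± 0.51. Apart from Acta2, the genes named in this paragraph kept their calls without each library.

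Of 25 matrix proteases and inhibitors 6 rose and 9 fell, 11 and 9 adjusted over the list alone, with a mean of -0.07 and so of the opposite sign to the median (median log2 fold change 0.46, camera adjusted p = 0.993). Mmp10 fell by 3.06 ± 0.53 and the protease inhibitor Timp1 fell by 1.15 ± 0.21. Of 25 TGF-beta targets 4 rose and 7 fell, 6 and 11 adjusted over the list alone (median log2 fold change -0.18, camera adjusted p = 0.469). Ctgf rose from 12.9 ± 5.07 to 39.5 ± 4.95 CPM and Tgfb2 by 2.30 ± 0.44. The change of Tgfb1 was -0.75 ± 0.25, called with the block and by DESeq2 (adjusted p = 0.0627, 0.00236 with the block, 0.0199 by DESeq2, 0.0262 without CM-JAKi replicate 1). Among 13 quiescent stellate and adipogenic genes 4 rose and 2 fell, 6 and 3 adjusted over the list alone, and the list was called with the block (adjusted p = 0.0474, or 0.335 with an estimated correlation as well) and without replicate 2 (0.0469) (median log2 fold change 0.97, camera adjusted p = 0.111). Cygb, a globin of stellate cells, rose by 2.17 ± 0.40. Of 19 fibroblast identity genes 3 rose and 5 fell, 5 and 5 adjusted over the list alone (median log2 fold change -0.08, camera adjusted p = 0.553). Ly6a fell from 138 ± 28.3 to 19.9 ± 6.51 CPM (adjusted p = 0.000329), Ly6c1 fell by 2.54 ± 0.29 and Pdpn fell by 1.31 ± 0.17, and Cd34 rose by 2.16 ± 0.38. Apart from Tgfb1, these genes kept their calls without each library.

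Of 40 cell cycle genes 3 fell, 11 with the block, where 2 rose. Adjusted over the list alone edgeR called 0 of them, against 8 lower and 1 higher at an unadjusted p under 0.05 and 6 lower by DESeq2 (median log2 fold change -0.09, camera adjusted p = 0.0934). Without replicate 1 that list was called lower (adjusted p = 0.00929). Bub1 fell by 0.40 ± 0.10 and lost its call without CM-JAKi replicate 2 (adjusted p = 0.0851), CM-JAKi replicate 3 (0.0549) or CM replicate 3 (0.0527). Of 14 genes of the list named for RNA quality, which does not measure RNA integrity, 0 were called by edgeR, by DESeq2 or at an unadjusted p under 0.05 (median log2 fold change -0.09, camera adjusted p = 0.508). Of 8 ductal markers 1 rose and 2 fell, of 5 leukocyte markers 1 fell, of 12 endothelial markers 3 rose, of 8 mesothelial markers 1 rose and 1 fell, and of 7 Schwann and neural markers 1 fell. Adjusted over the list alone the counts were 2 and 2, 0 and 1, 3 and 0, 1 and 1, and 1 and 1. The leukocyte marker that fell was Cd14, to 19.3 ± 9.03 CPM (adjusted p = 0.041), but not without CM replicate 1 (0.121), CM replicate 3 (0.0554), CM-JAKi replicate 2 (0.138) or CM-JAKi replicate 3 (0.117). None of these 5 lists was called (camera adjusted p = 0.670, 0.953, 0.487, 0.953 and 0.993). The endothelial list had a median of -0.07 and a mean of 0.80, and the mesothelial list -0.19 and 0.13, both with a higher camera direction.

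Whether the inhibitor opposed the response to conditioned medium was counted gene by gene. Of the 660 genes higher in CM, 536 (81.2%) were lower with the inhibitor, 3 were higher still and 121 were not called. Of the 734 genes lower in CM, 575 (78.3%) were higher with the inhibitor, 2 were lower still and 157 were not called. Independent lists of these sizes would share 59.0 and 73.8 genes. Both comparisons use the CM libraries, so their errors are shared. Across genes, which are not independent replicates, the changes had a Pearson r of -0.786, against -0.510 in 20 simulations with no effect, and a covariance of -0.466 against -0.0570, a difference of -0.409. Without MG-CM replicate 2 the counts were 41 and 75, without MG-CM replicate 1 338 and 315, and without CM replicate 1 248 and 281. They were 240 and 329 without MG-CM replicate 3, 265 and 249 without CM-JAKi replicate 2, and 328 and 384 without CM-JAKi replicate 3. With the block they were 1205 and 1396.

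Genes raised at least 2-fold in CM, 298 in number, had a median change of 1.69 in CM and of -1.96 with the inhibitor (SD of the 3 pair medians 0.197). Against MG-CM their median was -0.11, with 8 still higher and 50 lower than in MG-CM. The 331 genes lowered at least 2-fold had medians of -1.76 and 1.49 (SD of the pair medians 0.395), and against MG-CM -0.18, with 7 still lower and 3 higher. When the genes were picked with the block in 2 replicates and measured in the third, the median change with the inhibitor of raised genes was -1.78, -1.66 and -1.47. Of 392, 169 and 335 such genes, 92.3%, 94.7% and 94.3% moved opposite to their CM change. For lowered genes the medians were 1.90, 1.32 and 1.15. The largest products of opposite changes included Ifi44 among raised genes and Ptn among lowered genes. Ptn averaged 262 ± 111 CPM in MG-CM, 17.6 ± 11.3 in CM and 272 ± 119 with the inhibitor, and its CM call was lost without MG-CM replicate 2 (adjusted p = 0.0538).

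**Figure D3:**
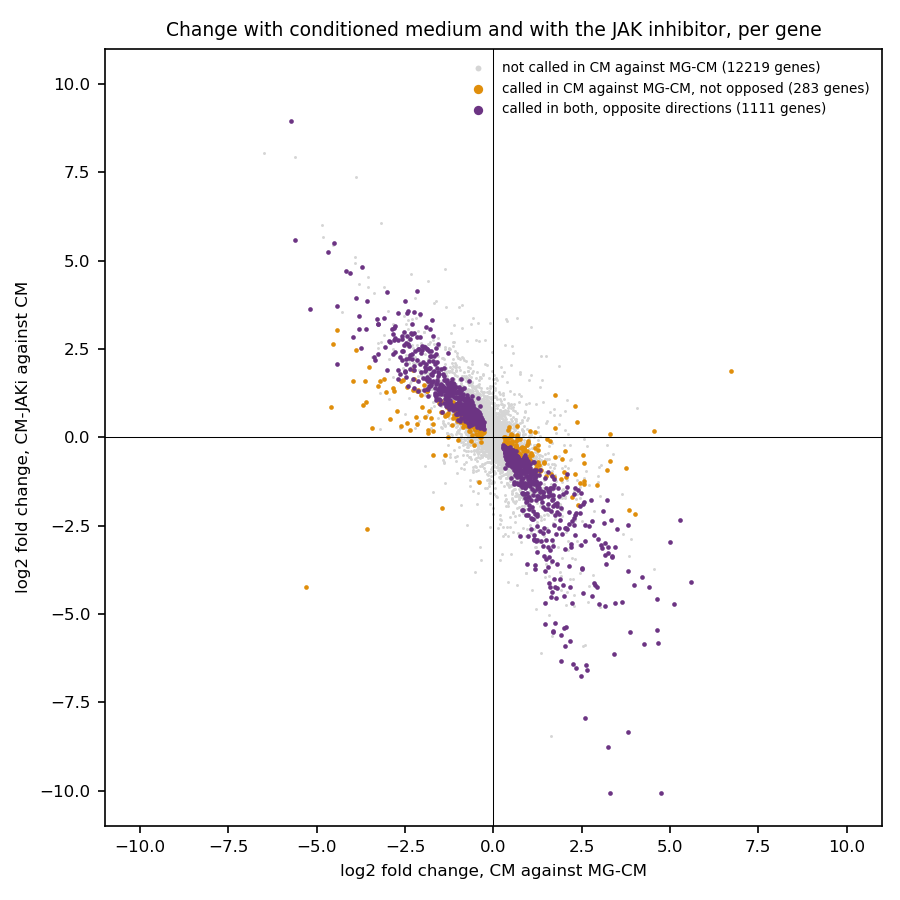
Log2 fold change in CM against MG-CM (x) and in CM-JAKi against CM (y) of each of 13613 genes, in grey where the gene was not called in CM, purple where it was called in both in opposite directions and orange for the rest. The 536 genes higher in CM and lower with the inhibitor lie at the lower right and the 575 genes lower in CM and higher with the inhibitor at the upper left.

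The comparison of CM-JAKi with MG-CM asks how cells in conditioned medium with the inhibitor differed from cells in control medium. Medium and inhibitor change together here, so a difference cannot be assigned to the medium or the inhibitor alone. Relative to control medium, most interferon response genes were lower. Few antigen presentation and JAK-STAT genes were called by edgeR, against 13 of 17 and 9 of 21 called lower by DESeq2. A small group of genes was higher, among them Dhrs3 and Mmp3. In all 39 genes were higher and 98 lower, 26 and 82 of them at least 2-fold, and all 137 moved in the same direction in 3 of 3 pairs. DESeq2 called 198 and 314 and the block gave 252 and 327. Of the 137 genes, 89 were also called in CM against MG-CM and 114 in CM-JAKi against CM. Of the 98 lower genes, 85 were lower than in CM as well, and 62 had been higher in CM than in MG-CM. Leaving out MG-CM replicate 3 left 8 higher and 41 lower, CM-JAKi replicate 2 11 and 21, and CM-JAKi replicate 3 16 and 34. The counts were 19 and 54 without MG-CM replicate 1 and 11 and 68 without MG-CM replicate 2. Of the 36 named genes called here, 14 were called without each library in turn.

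Of the 36 interferon response genes 24 fell below MG-CM, 32 adjusted over the list alone (median log2 fold change -2.08, camera adjusted p = 1.6e-51, adjusted p = 0.113 with an estimated correlation). Ifi44 averaged 19.4 ± 11.9 CPM in MG-CM and 0.42 ± 0.0821 with the inhibitor (adjusted p = 0.0043). The interferon pathway genes Irf9 and Usp18 fell (log2 changes -2.06 ± 0.19 and -2.76 ± 0.28), and Ifi27l2a fell by 3.79 ± 0.24. Of 17 antigen presentation genes 1 fell, Psmb8, with 14 adjusted over the list alone and 9 with the block (median log2 fold change -0.90, camera adjusted p = 1.82e-14, adjusted p = 0.113 with an estimated correlation). Psmb8 lost its call without CM-JAKi replicate 2 (adjusted p = 0.056). Of 21 JAK-STAT targets and receptors 4 fell, 10 adjusted over the list alone and 11 with the block (median log2 fold change -0.56, camera adjusted p = 1.82e-14, adjusted p = 0.113 with an estimated correlation). With the block and an estimated correlation together this list was called (adjusted p = 0.0441). Socs2 fell from 23.4 ± 2.97 to 2.13 ± 0.0639 CPM (adjusted p = 0.000482). Of 19 fibroblast identity genes 2 fell, Ly6a and Ly6c1 (log2 changes -2.53 ± 0.24 and -2.65 ± 0.29). Adjusted over the list alone 4 were lower and 1 higher, and the list call was lost with the block (adjusted p = 0.0588) and without replicate 2 (0.0746) (median log2 fold change -0.20, camera adjusted p = 0.024, adjusted p = 0.567 with an estimated correlation). Of 7 Schwann and neural markers 1 fell, 2 adjusted over the list alone (median log2 fold change -0.26, camera adjusted p = 0.0119, adjusted p = 0.383 with an estimated correlation), and the list lost its call with no low-count filter (adjusted p = 0.0578).

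Several lists were called higher or lower with few or no called members. Of 36 collagen and matrix genes edgeR called 0, against 7 higher and 2 lower at an unadjusted p under 0.05 and 4 and 2 by DESeq2 or adjusted over the list alone (median log2 fold change 0.25, camera adjusted p = 0.000881, adjusted p = 0.453 with an estimated correlation). Col1a1 was called with the block and by DESeq2 (log2 change 0.68 ± 0.16, adjusted p = 0.1, 0.0295 with the block, 0.00126 by DESeq2). Of 20 p53 and senescence genes edgeR called 0, with 3 higher at an unadjusted p under 0.05, 1 by DESeq2 and 1 adjusted over the list alone (median log2 fold change 0.33, camera adjusted p = 0.000881, adjusted p = 0.6 with an estimated correlation). Of 24 NF-kB targets edgeR called 0, with 7 higher and 1 lower at an unadjusted p under 0.05 and 2 higher by DESeq2 (median log2 fold change 0.24, camera adjusted p = 0.00141, adjusted p = 0.6 with an estimated correlation). Of 28 cholesterol and fatty acid synthesis genes edgeR called 0, with 2 higher at an unadjusted p under 0.05 and 0 by DESeq2, and the list lost its call without replicate 1 (adjusted p = 0.423) (median log2 fold change 0.12, camera adjusted p = 0.00966, adjusted p = 0.8 with an estimated correlation). Of 32 ribosomal protein genes edgeR called 0, with 1 lower at an unadjusted p under 0.05 and 0 by DESeq2 (median log2 fold change -0.19, camera adjusted p = 2.89e-05, adjusted p = 0.8 with an estimated correlation). Of 27 inflammatory fibroblast genes 1 rose, with 2 higher and 1 lower adjusted over the list alone and 3 and 1 with the block, and the list lost its call without replicate 1 (adjusted p = 0.427) (median log2 fold change 0.40, camera adjusted p = 0.0386, adjusted p = 0.8 with an estimated correlation). The gene that rose was Cxcl16, from 41.8 ± 8.09 to 85.5 ± 17.4 CPM, and leaving out a single library ended its call for 5 of the 6, with MG-CM replicate 1 the exception (adjusted p = 0.16, 0.159, 0.0692, 0.103 and 0.106 without MG-CM replicates 2 and 3 and CM-JAKi replicates 1, 2 and 3). Il6, Lif, Acta2 and Jak1 were not called (adjusted p = 0.874, 0.264, 0.939 and 0.0728, log2 changes 0.75 ± 0.91, 1.93 ± 0.61, -0.34 ± 0.74 and -0.43 ± 0.09).

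The other 15 lists were not called against MG-CM, with camera adjusted p values from 0.147 to 0.97, but without replicate 1 the cell cycle list (adjusted p = 0.000819) and the oxidative stress list (0.0143) were called. The ductal list had a median of 0.16 but a lower test direction, the protease list a median of -0.04 and a mean of 0.23, and the pericyte list a median of 0.12 and a mean of -0.01. For 22 contractile genes edgeR called 0, as did DESeq2 and an unadjusted p under 0.05, with a median of -0.15. Among genes higher than in MG-CM, Dhrs3, which encodes a retinal reductase, averaged 8.77 ± 3.01 CPM in MG-CM, 43.8 ± 12.4 in CM and 80.7 ± 32.2 with the inhibitor (log2 change 3.20 ± 0.36, adjusted p = 0.00581). Adam22 rose by 1.33 ± 0.14, and both kept their calls without each library. Mmp3 averaged 290 ± 124 CPM with the inhibitor (adjusted p = 0.0239), a call lost without MG-CM replicate 2 (0.097), MG-CM replicate 3 (0.0938) or CM-JAKi replicate 2 (0.0917). Because no library combined control medium with the inhibitor, the inhibitor's effect outside conditioned medium was not measured.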

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

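The tests of interferon genes, of metabolic lists and of sequencing depth in this part were chosen after the results were seen, and the test of line and medium source before. Named genes whose response differed between PSC4 and PSC5 were looked at more closely. The difference was tested as an interaction in the replicate block fit (adjusted p under 0.05) and rests on a single PSC4 library per group, which also had its own medium source. Its 2 residual degrees of freedom come from PSC5-I against PSC5-II alone. In CM against MG-CM 372 genes differed, 97 of them with a higher and 275 with a lower change in PSC4, and in CM-JAKi against CM 282 differed, 211 and 71. In CM-JAKi against MG-CM edgeR called 0, with 875 at an unadjusted p under 0.05.

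In CM against MG-CM the log2 change in PSC4 minus that in PSC5 was negative for 12 of 18 named genes. It was -2.30 for Acta2 (adjusted p = 0.0308), -1.95 for Lmod1, -0.88 for Vcl, -3.76 for Osr2 (adjusted p = 0.00619), -3.74 for Scn7a, -2.61 for Fmod and -2.16 for Figf (adjusted p = 0.00336). It was -1.89 for Vit, -1.44 for Tubb3, -0.87 for Ptn, -0.83 for Tgfbr2 and -0.81 for Cygb. The difference was positive for Lif (2.18), Ero1l (1.15), Cd14 (1.13), Nsdhl (0.84), Sod2 (0.73) and Rpl5 (0.61).

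In CM-JAKi against CM the signs were turned for genes that differed in both. The difference was 4.53 for Fmod (adjusted p = 0.012), 3.25 for Scn7a, 2.74 for Olfml2a, 2.66 for Acta2, 2.13 for Lmod1, 1.99 for Wnt10a, 0.89 for Ptn and 0.88 for Tgfbr2. It was -1.27 for Plaur, -1.15 for Ero1l and -0.79 for Rpl5. The CM library is shared by both comparisons, so a deviation in CM replicate 1 appears in both with opposite signs.

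The CM change was larger in the PSC4 pair as a whole. The SD of log2 changes over genes was 0.879 in replicate 1, 0.70 in replicate 2 and 0.608 in replicate 3, and 1967, 1328 and 1100 genes changed at least 2-fold. Sequencing depth is argued against: with every library thinned to 25625806 counts in 20 random draws, the SD was at least 0.871 in replicate 1 and at most 0.701 in the other pairs. The 372 genes that differed may reflect the stellate line, the medium source or a single deviating culture such as CM replicate 1. These cannot be told apart, because each replicate had its own source and PSC4 was used once per group.

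Of 36 interferon response genes 24 lay below their MG-CM level with the inhibitor, and the call of the list was lost with an estimated correlation (adjusted p = 0.113). Fry called the list lower (fry adjusted p = 0.00802, or 0.0274 with the block). A scaling effect is argued against: the median change of the list was -2.02 with TMM, -2.03 with DESeq2 size factors and -1.999 with library size alone. These medians are of differences in mean log2 CPM, while the median of -2.08 given above is of edgeR fold changes. Counts near the floor are argued against by the median MG-CM level of 51.2 CPM of the 36 members tested, called or not. The PSC4 pair alone is argued against by medians of -2.50, -1.65 and -1.87 in the 3 pairs, of which -1.65 is the nearest to 0 outside replicate 1. A JAK-dependent interferon signal already present in control medium may therefore explain the pattern, but without control medium with the inhibitor this was not tested.

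Of the members of the cholesterol, amino acid and hypoxia lists, 21 of 28, 13 of 30 and 14 of 32 rose in CM and 18, 18 and 19 fell with the inhibitor. The calls of these lists were lost with an estimated correlation (adjusted p = 0.332 for each in CM and 0.385 for each with the inhibitor). Fry called each list higher in CM (fry adjusted p = 0.0203, 0.0406 and 0.0289, in the same order). It called each lower with the inhibitor (0.0243, 0.0243 and 0.0190). With the block the amino acid list missed the threshold in CM (fry adjusted p = 0.0578). Of the median CM change of the 48 raised members, 10.7%, -0.632% and -16.1% was left with the inhibitor in the 3 pairs. These shares cannot decide on medium composition acting without JAK activity. A separate lowering of the same genes by the inhibitor would leave the same shares, and no library combined control medium with the inhibitor. The larger median change of the 13 mitochondrial transcripts was -0.0904, which speaks to mitochondrial content only. RNA integrity was not measured, so a shift in RNA quality cannot be decided. A cell cycle shift as large as that of the metabolic lists is argued against by the 40 cell cycle genes, whose larger median change was -0.0912. A smaller one is not excluded. With the block 11 of these genes were lower and 2 higher in CM-JAKi against CM. Without replicate 1 camera called the list lower there (adjusted p = 0.00929) and against MG-CM (0.000819). A JAK-dependent metabolic response to the medium may remain, as may an effect of the inhibitor on these genes outside conditioned medium, which was not tested.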

How the results depend on the processing

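Alternatives that combine the replicate block with an estimated correlation, with leave-outs or with the picking of genes were chosen after seeing the data. No called gene of any comparison changed sign with the block, the line term, another test, scaling or filter, only the groups compared, or in leave-outs without the block, and 1393 of 1394, 2579 of 2585 and 137 of 137 called genes stayed called with the block. For CM against MG-CM the 660 higher and 734 lower genes became 1573 and 1747 with the block, 1551 and 1665 with a cell line term, 1207 and 1309 by DESeq2, and 362 and 431 in a fit of only the groups compared, which has fewer samples. Leave-outs gave 6 to 1342 higher and 2 to 1446 lower genes. For CM-JAKi against CM the 1369 and 1216 genes became 2529 and 2126 with the block and 2422 and 2110 with the line term, and 836 higher genes were called with only the groups compared. Leave-outs gave 76 to 2212 and 180 to 1980. For CM-JAKi against MG-CM the 39 and 98 genes became 252 and 327 with the block, 229 and 294 with the line term and 198 and 314 by DESeq2, and limma-voom gave 65 lower genes. Leave-outs gave 0 to 510 and 0 to 485, with the 0 from edgeR without replicate 3, where DESeq2 and unadjusted counts were not taken. The opposition counts of 536 and 575 became 1205 and 1396 with the block, 1198 and 1319 with the line term and 922 and 999 by DESeq2. Leave-outs gave 5 to 999 and 2 to 1072. The highest counts of these ranges came from leave-outs within the block fit. The median change with the inhibitor of CM-raised genes, -1.96, was -1.68 with the block and -0.87 without the 2-fold threshold, which admits smaller changes. It was -1.51 and -1.05 for the 6 and 23 genes picked outside replicates 2 and 3, and -1.66 and -1.47 when these were picked with the block. That of CM-lowered genes, 1.49, was 0.82 without the threshold, 2.00 and 2.52 for the 359 and 2 genes picked outside replicates 1 and 2, and 1.90 outside replicate 1 with the block. Leave-outs gave -2.58 to -1.68 and 1.44 to 2.85. Gene lists called numbered 13, 12 and 11, and 0 in each comparison with an estimated correlation. With the block and an estimated correlation together they numbered 0, 0 and 1, and fry called 3 in CM-JAKi against MG-CM. With fry the JAK-STAT (adjusted p = 0.136), acute phase (0.303), NF-kB (0.146) and p53 (0.136) lists lost their calls in CM against MG-CM. In CM-JAKi against CM the inflammatory (0.0868) and ribosomal (0.187) lists lost theirs and the quiescent list gained one (0.0244), and in CM-JAKi against MG-CM 8 of 11 lists lost theirs (0.121 to 0.672). Leave-outs gave 11 to 17, 12 to 13 and 10 to 11 lists. Other scalings and filters kept each count within 1.5 times. For named genes, 3042 of 3940 leave-out values kept direction and call, 794 lost the call, 58 gained it, 46 uncalled values changed sign and 0 called values did. Under the other alternatives 3203 of 3456 were kept, 74 lost and 171 gained the call, 8 uncalled values changed sign and 0 called ones did. Apart from the fit of only the groups compared, the leave-outs and the fold threshold, the cause was not tested. The block changed no other call of a described gene or list than those given. Counts limited few genes, and those with 3 or fewer counts in a group moved no list median.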

Other observations

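The tests in this part were chosen before their results were seen, but the requirement below that the fatty acid list also be higher in CM was added after.

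Genes of metal and glutathione handling moved apart. Of 20 oxidative stress and metal response genes 3 rose and 2 fell in CM, 5 and 4 adjusted over the list alone (median log2 fold change 0.10, camera adjusted p = 0.667). Gstm1, a glutathione transferase, fell by 1.80 ± 0.22 in CM (adjusted p = 0.00734) and rose by 1.96 ± 0.22 with the inhibitor, in 3 of 3 pairs each. Slc7a11, the cystine transporter, rose by 2.47 ± 0.49 and then fell by 3.06 ± 0.50, and the metallothionein Mt2 rose by 2.19 ± 0.54 and fell by 3.11 ± 0.56. The rise of Slc7a11 was not called without MG-CM replicate 1 (adjusted p = 0.0579) or MG-CM replicate 2 (0.0873). That of Mt2 was not called without CM replicate 1 (0.1), CM replicate 3 (0.0539), MG-CM replicate 2 (0.144) or MG-CM replicate 3 (0.108). With the inhibitor 2 genes of the list rose and 5 fell, 3 and 5 adjusted over the list alone (median log2 fold change -0.21, camera adjusted p = 0.228).

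The counts of called genes were set against other splits of the same 6 libraries. The 10 splits are too few for a share under 0.05. In CM against MG-CM 1 of the 10 splits, the real one, called as many as 1394 genes, and the highest other split called 0. In CM-JAKi against CM it was 1 of 10 with 2585 genes, and in CM-JAKi against MG-CM 1 of 10 with 137 genes, with 0 as the highest other count in both.

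Tumour epithelial cells carried over in the medium may raise genes in CM. A list of 8 epithelial genes summed to at most 0.785 CPM in a CM library, and to 0.206 to 1.05 CPM over all 9 libraries, which argues against carried-over cells as the source of the raised genes.

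The retinoid genes Dhrs3 and Rarb were higher in CM-JAKi than in MG-CM, by 3.20 ± 0.36 and 2.81 ± 0.42 (adjusted p = 0.00581 and 0.0212, 3 of 3 pairs each). The call of Rarb was lost without MG-CM replicates 1, 2 and 3 in turn (adjusted p = 0.0777, 0.0877 and 0.0938) and without CM-JAKi replicates 2 and 3 (0.0854 and 0.0735). A retinoic acid response to the medium that does not need JAK may explain this. Of 12 other targets 9 were tested, and the list had a limma fry p of 0.592 in that comparison (median 0.02). A p of 0.05 or more had been set as evidence against the hypothesis. That bound was wrong, because a missed p excludes nothing and the changes of single members in that comparison had wide errors on both sides of 0, from -0.61 ± 0.44 for Rarres1 to 0.97 ± 0.79 for Cyp26b1. In CM against MG-CM, where a response to the medium should also raise the list, its fry p was 0.265 (median 0.36). There 0 of its genes were called higher and 1 lower, Rarres1 (log2 change -2.49 ± 0.47, adjusted p = 0.0182). The hypothesis stays open, without support from these other targets.

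Angptl4, a target of fatty acid receptors, was higher in CM-JAKi than in MG-CM by 2.03 ± 0.29 (adjusted p = 0.0167, 3 of 3 pairs), a call lost without MG-CM replicate 1 (adjusted p = 0.0534), MG-CM replicate 2 (0.0702), CM-JAKi replicate 2 (0.0531) or CM-JAKi replicate 3 (0.0567). A response of these receptors to the medium that does not need JAK may explain it. The list of 12 other targets was higher in that comparison (median 0.26, 1 gene higher, with a limma fry p of 0.00117, adjusted p = 0.00352 over the 6 tests of both lists), as the hypothesis predicted, and the gene called, Cpt1a, rose by 0.62 ± 0.09. A response to the medium should also raise the list in CM without the inhibitor, where it was not called (median -0.17, 2 genes higher and 2 lower, fry adjusted p = 0.168), and with the block it was called lower (adjusted p = 8.81e-04). With the inhibitor it was higher than in CM (median 0.39, 4 genes higher and 1 lower, fry adjusted p = 0.00135), and Pdk4 rose by 1.09 ± 0.24. Whether the inhibitor or the medium raised the list cannot be told apart without control medium with the inhibitor.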
